A study of Mus musculus with 18 samples.

How the data were processed

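RNA was measured by sequencing in the liver, brain and testis of mice under chronic restraint stress, in which animals are held confined, and of control mice. Each of the 6 groups (3 tissues, control or stress) had 3 replicate libraries, 18 libraries in all. Per the labels, libraries were made from total RNA with a stranded total RNA kit, and the reads were placed on mouse genome build mm39. The aligner, the counting program, the strand setting and the annotation release are not given in the sources used here. The extraction text in the labels speaks of hippocampus where the sample labels say brain, and the tissue is called brain here. The description of stress brain replicate 3 carries a code with the prefix of the control samples, while its title, its treatment and its column in the table say stress, and it was kept in the stress group.

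The deposited table holds 34932 genes with raw counts, TPM and FPKM in each library. The counts were deposited as whole numbers without normalization. The FPKM values were made by the authors from these counts with 1 fixed length per gene and the column total. The TPM values were made by the authors from the same counts and lengths and sum to the same total in each library. Tests used the counts, and TPM served as an alternative scale. Total counts per library ranged from 27.85 to 36.5 megacounts. Pairs of replicates of the same group differed by more than counting error, with a chi-square per degree of freedom across genes of 4.64 to 114.72, so errors are given as SD between libraries or SE from the fitted model. Symbols and gene classes came from GENCODE mouse release M21 (build GRCm38) by gene identifier, which named 34362 genes and left 570 without a symbol. That release belongs to another build than the one the labels name, so no genome positions are given.

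Stress was compared with control within each tissue with edgeR 4.0.16 in R 4.3.3 (TMM factors, default filter on low counts, quasi-likelihood test), with Benjamini-Hochberg adjustment over the genes tested and a threshold of 0.05. CPM values are counts scaled to library size and corrected by TMM factors, except in the sums of tissue markers, which used library size alone. Log2 fold changes are stress minus control. Of 72 gene lists of pathways, cell types and quality markers, those that fit the tissue and had at least 5 tested genes were tested with camera of limma 3.58.1, with a preset correlation of 0.01 between genes and Benjamini-Hochberg adjustment over the lists of the tissue. Each list was tested again with the correlation estimated from the data and with fry. The difference of the stress effect between tissues was tested in edgeR as an interaction over the 12 libraries of each pair of tissues. Overlap between tissues was tested with Fisher's exact test, one-sided. The comparisons, lists, alternatives and the rule for named genes were fixed before the data were examined. The rule took Fkbp5, Tsc22d3, Per1, Sgk1 and Nr3c1 in every tissue, the 10 higher and the 10 lower called genes with the largest change among those whose groups did not overlap and whose mean CPM reached 1 in a group, and up to 4 members with the smallest p of each list described. Predicted genes, pseudogenes and small RNA genes were passed over. Where fewer than 5 genes passed in a direction, the genes with the smallest p filled the list up to 5. The rule also took the 5 genes with the smallest adjusted p per pair of tissues. Any other gene named was chosen after its values were seen.

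The same sample codes recur in the 3 tissues, so a fit with animal as a block stands beside each difference between tissues. Correlations across genes of the deviations from the group mean tested whether replicate numbers pair control with stress libraries. In brain they were 0.371, 0.283 and 0.582 for libraries of the same number, so a fit with the replicate number as a block stands beside the brain results. In liver they were 0.261, 0.053 and 0.037, and in testis 0.12, 0.121 and -0.148, which gave no such pairing. The codes of control and stress samples name no pairs, so the pairing in brain was read from these same libraries. A block kept for that reason can make its p values too small.

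The test was tested on simulated data with 200 changed genes. At a true 2-fold change it recovered 52% of genes in liver, 66% in brain and 54% in testis, and at a true 4-fold change 84%, 81% and 86%. False calls were 17 of 153 in liver, 11 of 158 in brain and 10 of 150 in testis, and with no changed gene 0 were called. The interaction test recovered 82%, 78% and 85.5% of genes with a 4-fold difference for liver and brain, liver and testis, and brain and testis. Its false calls were 17 of 181, 12 of 168 and 19 of 190 in the same order. Genes and tissues were simulated independently of each other. Real genes vary together and the tissues were taken to share animals, so false calls in the data can be more frequent. Alternatives were DESeq2 1.42.0, its size factors in edgeR, limma-voom, limma on log2 TPM with pseudocounts of 1 and 0.1, no filter and a stricter filter on low counts, all 18 libraries in 1 fit, a 2-fold minimum, the replicate block and leaving out each library. A fit without stress brain replicates 2 and 3 together was added after the data were seen. Sequence reads were not analysed here.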

Results

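Transcript levels were measured in 18 RNA sequencing libraries from mouse liver, brain and testis. Chronic restraint stress is a model of lasting psychological stress in which animals are kept confined, and control animals were not restrained. Each tissue had 3 control and 3 stress libraries. Total counts per library, in megacounts, ranged from 31.87 to 35.1 in control liver, from 29.95 to 33.2 in stress liver, from 32.38 to 36.5 in control brain and from 32.08 to 34.08 in stress brain. In testis they ranged from 27.85 to 31.38 in control and from 28.51 to 33.48 in stress.

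Marker genes separated the tissues. Hepatocyte markers summed to 84740 CPM or more in every liver library, against at most 503.4 CPM in brain and 6.98 CPM in testis. The 503.4 CPM was in stress brain replicate 2, where Ttr, a member of that list and also a choroid plexus marker, alone had 492 CPM. Neuron markers summed to at least 10650 CPM in brain, and germ cell markers to at least 16080 CPM in testis.

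The liver comparison asked which transcripts of this metabolic organ differ between stressed and control mice. Among the genes higher in stress liver were 3 that glucocorticoid hormones are known to induce. Zbtb16 (ENSMUSG00000066687), a transcription factor gene, rose from 3.10 ± 0.843 to 34.05 ± 15.13 CPM (mean ± SD, n = 3 per group), a log2 fold change of 3.46 ± 0.35 (SE; edgeR adjusted p = 0.00351). Tsc22d3 (ENSMUSG00000031431), which encodes the leucine zipper protein GILZ, rose from 51.6 ± 14.15 to 174 ± 27.67 CPM, and Fkbp5 (ENSMUSG00000024222), a co-chaperone of the glucocorticoid receptor, rose from 14.4 ± 3.01 to 45.68 ± 12.22 CPM (edgeR adjusted p = 0.00722 and 0.0108). As lists, genes of cholesterol and fatty acid synthesis and immediate early genes were lower, and markers of macrophages and heat shock proteins were higher in the camera test. These calls were lost with an estimated correlation (adjusted p between 0.516 and 0.631). Per1, Sgk1 and Nr3c1, the last encoding the glucocorticoid receptor, had log2 fold changes of 0.25, -0.73 and -0.09 that did not pass (edgeR adjusted p = 0.701, 0.0747 and 0.862). The list of glucocorticoid-induced genes as a whole did not pass, with 3 of 23 tested members higher and 0 lower over all genes in edgeR, and 4 higher and 5 lower when adjusted over the list alone. Its median log2 fold change was -0.03 and its mean -0.18, while the test's sign was upward, and downward with the replicate block (camera adjusted p = 0.978 and 0.964).

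In the liver, 140 genes were higher and 92 were lower in stress among 14253 tested with edgeR, and 95 and 59 of them changed at least 2-fold. An unadjusted p under 0.05 was found for 2445 genes against 712.7 expected by chance. Control and stress values did not overlap in 3284 of all tested genes (23%), where chance gives 10% on average. Genes vary together, so in any tissue a single grouping can lie far from both chance values without an effect of stress. Next to Zbtb16, the largest increases under the rule for named genes were Guca1b (log2 fold change 4.34), Hapln1 (3.87), Ugt1a9 (2.85), Hist2h4 (2.70), Hspb1 (2.44), Angptl4 (2.36), Mroh6 (2.34), Hist2h3c2 (2.33) and Cyp21a1 (2.30). Angptl4 encodes an inhibitor of lipoprotein lipase and rose from 24.54 ± 4.295 to 125.7 ± 29.31 CPM (edgeR adjusted p = 0.00207). The largest decreases were Nr4a3 (-4.78), Cfd (-4.54), Eps8l1 (-4.18), Fam83f (-3.90), Cib3 (-3.64), Fosb (-3.50), Pnpla3 (-3.41), Socs3 (-3.24), Tchh (-2.81) and Myc (-2.74). Socs3, a feedback inhibitor of cytokine signalling, fell from 120.4 ± 5.775 to 12.71 ± 7.768 CPM (edgeR adjusted p = 0.00498). Without stress replicate 3 the counts were 15 higher and 16 lower, and without stress replicate 1 they were 39 and 22. Without control replicate 2 they were 44 and 37, without control replicate 3 they were 56 and 50, and 89 genes were higher without stress replicate 2. Genes named only as list members were not part of the tally that follows. Of the 22 genes that passed in liver among those always taken and the largest changes, 9 passed whichever library was left out (Fkbp5, Tsc22d3, Zbtb16, Angptl4, Eps8l1, Cib3, Fosb, Socs3 and Tchh). The other 13 missed the threshold in at least 1 such fit, with a largest edgeR adjusted p between 0.0579 for Ugt1a9 and 0.201 for Hist2h4. Each of the 6 libraries ended at least 1 of these calls when left out, and Cfd was lost in every such fit.

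Genes of lipid synthesis were lower as lists in the liver. In the list of cholesterol biosynthesis, 25 of 25 members were lower, with a median log2 fold change of -0.79 (camera adjusted p = 1.07e-11; adjusted p = 0.631 with an estimated correlation). Of these, 4 passed over all genes and 21 when adjusted over the list alone. Hmgcs1, a synthase early in the pathway, fell by 1.54 ± 0.23 on the log2 scale (SE, edgeR adjusted p = 0.0192), Msmo1 fell by 1.39 and Mvd fell by 1.32. In the lipogenesis list, 5 of 20 members passed, 11 were lower and 1 higher when adjusted over the list alone, and the median was -0.61 (camera adjusted p = 6.3e-06; adjusted p = 0.631 with an estimated correlation). Scd1, which desaturates fatty acids, fell from 6857 ± 1525 to 1436 ± 389.2 CPM (edgeR adjusted p = 0.00461), Srebf1, the transcription factor gene of the pathway, fell by 1.30, Pltp fell by 2.06 and Me1 fell by 1.04 on the log2 scale. The glycolysis list was lower, with 0 of 16 members passing, 8 at an unadjusted p under 0.05 and 6 adjusted over the list alone in edgeR, and a median of -0.23 (camera adjusted p = 0.0392; adjusted p = 0.631 with an estimated correlation). That call was lost without control replicate 1 or stress replicate 1, with an adjusted p of up to 0.121, and with the replicate block (0.0605). Pck1, the key enzyme of gluconeogenesis, rose from 1655 ± 267 to 3776 ± 422.7 CPM (edgeR adjusted p = 0.0119), while its list of fasting response genes did not pass (camera adjusted p = 0.44).

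Immediate early genes, which respond quickly to stimuli, were lower in 20 of 21 tested members in the liver, with a median of -1.79 (camera adjusted p = 6.77e-11; adjusted p = 0.631 with an estimated correlation). Fosb and Nr4a3 passed over all genes and 13 members when adjusted over the list alone. Fosb fell from 26.18 ± 3.387 to 2.30 ± 1.966 CPM, and Nr4a1 had 275.8 ± 32.98 CPM in control and 19.15 ± 25.24 CPM in stress without passing (edgeR adjusted p = 0.0116 and 0.0534). The list's median per library, relative to controls, was -2.77, -0.73 and -2.95 in stress replicates 1, 2 and 3. Heat shock proteins and chaperones were higher in 19 of 20 members, with a median of 0.61 (camera adjusted p = 6.3e-06; adjusted p = 0.631 with an estimated correlation). In that list, 4 passed over all genes and 8 when adjusted over the list alone. Hspb1 rose from 36.55 ± 24.13 to 198.3 ± 108.5 CPM, and Hspa4l, Stip1 and Ahsa1 rose by 1.23, 0.85 and 0.60 on the log2 scale (edgeR adjusted p = 0.0476, 0.0223, 0.0347 and 0.0476 for the 4 genes). Per2, a clock gene, rose by 1.22 ± 0.15 on the log2 scale (SE, edgeR adjusted p = 0.00827), and the clock gene list did not pass (camera adjusted p = 0.387).

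Markers of macrophages, which in liver are mainly Kupffer cells, were higher, with 9 of 15 members passing over all genes and 12 when adjusted over the list alone. Their median log2 fold change was 1.15 (camera adjusted p = 1.07e-11; adjusted p = 0.516 with an estimated correlation; fry adjusted p = 0.00963), and all 3 stress libraries had list medians above all 3 controls. Cd163, a scavenger receptor of macrophages, rose from 2.76 ± 0.666 to 9.27 ± 0.439 CPM, and the complement genes C1qa and C1qc and the receptor gene Csf1r rose by 1.23, 1.15 and 1.11 on the log2 scale (edgeR adjusted p = 0.00913, 0.0108, 0.0108 and 0.0147). The antigen presentation genes Cd74, H2-Ab1 and H2-Eb1 rose by 1.32, 1.25 and 1.41 (edgeR adjusted p = 0.0235, 0.0359 and 0.0359), and their list did not pass (camera adjusted p = 0.0671, and 0.0334 with the replicate block; adjusted p = 0.634 with an estimated correlation and the block). Endothelial markers were lower with a median of -0.63, 0 of 14 members passing and 5 at an unadjusted p under 0.05 in edgeR (camera adjusted p = 0.0187; adjusted p = 0.631 with an estimated correlation). That call was lost without control replicate 1, control replicate 3 or stress replicate 3, with an adjusted p of up to 0.251. Lists of lymphocyte and of red cell markers did not pass (camera adjusted p = 0.117 and 0.112, and 0.0271 and 0.13 with the replicate block). For lymphocyte markers it was 0.634 with an estimated correlation and the block.

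Camera called 7 further lists in the liver. Replication-dependent histones were higher with a median of 0.65, and 2 of 7 members passed, Hist2h3c2 and Hist2h4 (camera adjusted p = 0.00311; adjusted p = 0.516 with an estimated correlation; fry adjusted p = 0.00859). Male-biased growth hormone-dependent genes were higher with a median of 0.28 (camera adjusted p = 0.00262; adjusted p = 0.631 with an estimated correlation), and 1 of 22 members passed, the complement gene C4a, which rose by 2.05 ± 0.16 on the log2 scale (SE). Interferon-stimulated genes were higher with a median of 0.20 (camera adjusted p = 0.0276; adjusted p = 0.631 with an estimated correlation), and 1 of 30 passed, Oas2, which rose by 1.78 ± 0.26. Drug-metabolizing enzymes were higher with a median of 0.17, with 0 of 38 passing, 12 higher and 1 lower at an unadjusted p under 0.05 and 7 higher when adjusted over the list alone in edgeR (camera adjusted p = 0.0021; adjusted p = 0.631 with an estimated correlation). Ribosomal protein genes (median -0.19, camera adjusted p = 3.24e-05), mitochondrially encoded mRNAs (-0.33, 0.00134) and nuclear genes of oxidative phosphorylation (-0.10, 0.0123) were lower. With an estimated correlation their adjusted p was 0.631, 0.631 and 0.639. Without control replicate 1 the adjusted p was 0.132 for ribosomal proteins and 0.218 for the male-biased list. It reached 0.186 for interferon-stimulated genes without control replicate 1 or stress replicate 1. It reached 0.42 for oxidative phosphorylation without control replicate 1 or stress replicates 2 or 3.

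**Figure D1:**
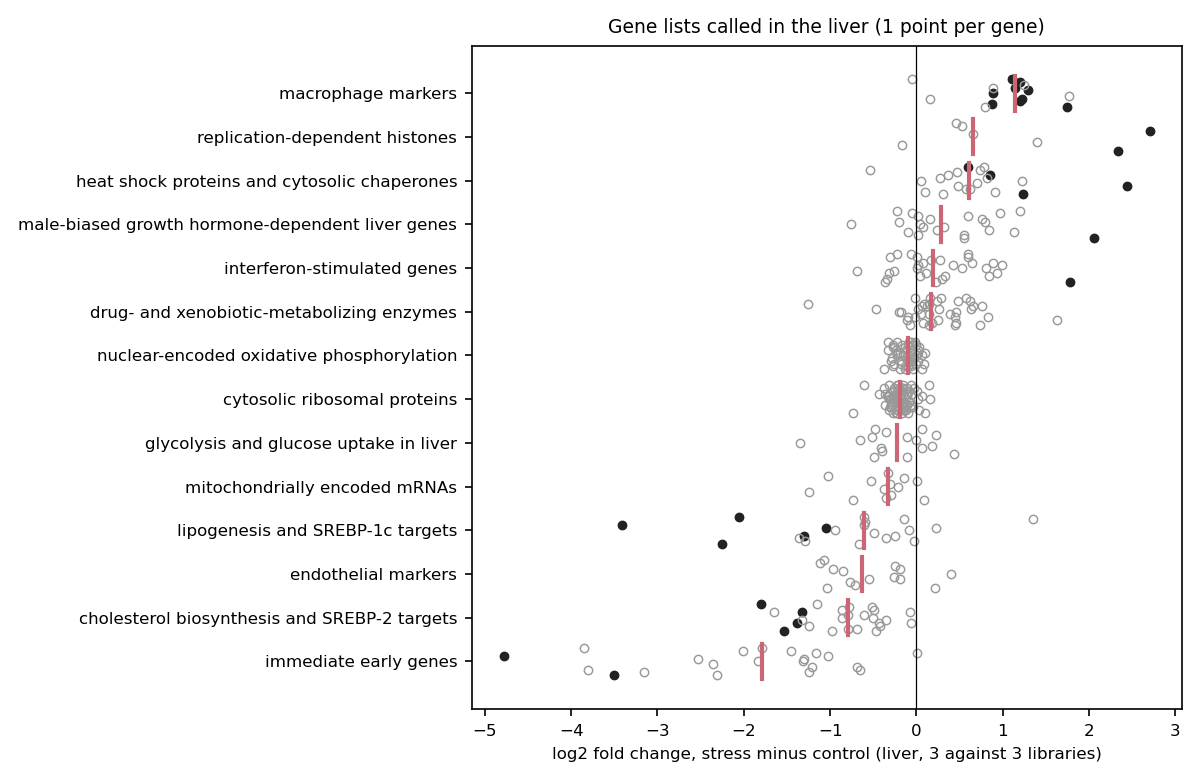
Log2 fold changes (stress minus control, x axis) of the tested genes of the 14 lists that camera called in the liver, with filled points for an edgeR adjusted p under 0.05 and a red bar at each list's median. Medians ran from -1.79 for immediate early genes to 1.15 for macrophage markers.

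The brain comparison asked for the same differences in nervous tissue. As lists, heat shock proteins, endoplasmic reticulum stress genes, glucocorticoid-induced genes and markers of astrocytes and of the choroid plexus were higher in stress brain, and immediate early genes, mitochondrial mRNAs and cortical markers were lower. No member of these lists passed over all genes without the replicate block. The list calls of camera were lost with an estimated correlation (adjusted p of 0.571 or more). Heat shock proteins were higher in 20 of 20 members, with a median log2 fold change of 0.30 (camera adjusted p = 2.68e-11; adjusted p = 0.571 with an estimated correlation), and 11 passed when adjusted over the list alone. Hspa1b, an inducible heat shock protein gene, had 17.95 ± 4.008 CPM in control and 49.78 ± 11.56 CPM in stress (n = 3 per group), and Hspb1 and Hspa1a had log2 fold changes of 1.10 and 1.12, none of which passed over all genes (edgeR adjusted p = 0.351, 0.357 and 0.387). Glucocorticoid-induced genes had a median of 0.18 (camera adjusted p = 0.000435; adjusted p = 0.571 with an estimated correlation), with 6 members higher and 2 lower when adjusted over the list alone. Fkbp5 had 29.25 ± 4.217 CPM in control and 53.09 ± 8.492 CPM in stress, a log2 fold change of 0.86 ± 0.15 (SE) with an edgeR adjusted p of 0.385, and of 0.012 with the replicate block. Zbtb16 had a log2 fold change of 0.87 with an edgeR adjusted p of 0.611, and of 0.0403 with the block. Dusp1, of the same list, went the other way, with a log2 fold change of -1.005 (edgeR adjusted p = 0.532, and 0.0238 with the block). The adjusted p values with the block rest on a pairing read from these same libraries and can be too small. The values for Tsc22d3, Per1, Sgk1 and Nr3c1 were 0.24, -0.02, -0.09 and -0.22, none of which passed (edgeR adjusted p = 0.638, 0.99, 0.924 and 0.724).

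Single genes in the brain seldom passed over all genes. Of 17668 genes tested with edgeR, 1 was higher and 0 were lower, with 1332 at an unadjusted p under 0.05 against 883.4 expected by chance. Control and stress values did not overlap in 13.8% of the tested genes, where chance gives 10% on average. DESeq2 called 93 higher and 44 lower, limma-voom 0 and 0, and edgeR with the replicate block 17 higher and 5 lower. The gene called was Gm6969 (ENSMUSG00000066553), a processed pseudogene outside the rule for named genes and chosen after its values were seen, which rose from 0.609 ± 0.297 to 22.69 ± 6.748 CPM (edgeR adjusted p = 0.0252, 0.000145 with the block). With control replicate 1, 2 or 3 or stress replicate 1 or 2 left out it did not pass and the count was 0 genes, and without stress replicate 3 it passed. Genes with the smallest p that did not pass were Rpl38, Ddo, Serpinh1, Atp5k and Hspa1b on the higher side (log2 fold changes 0.69, 1.31, 0.69, 0.69 and 1.47) and Cldn5, Zfp945, Fhl2, Rsph10b and Gpr21 on the lower side (-0.55, -0.69, -0.53, -0.97 and -1.03). With the block Rpl38, Atp5k and Ddo passed (edgeR adjusted p = 0.012, 0.0193 and 0.037), as did the immediate early genes Btg2 and Npas4 with block log2 fold changes of -1.67 and -1.46 (adjusted p = 0.012 for both). The hemoglobin genes Hba-a1 and Hbb-bs passed as well, with -1.181 and -0.855 (edgeR adjusted p = 0.012 and 0.033 with the block). So did Ttr, Trh, Lhx9 and C1ql2, with 6.975, 2.855, 2.385 and 2.212. The calls with the block thus also took in red cell and choroid plexus markers.

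Genes of endoplasmic reticulum stress and the unfolded protein response were higher in the brain with a median of 0.18 (camera adjusted p = 4.16e-05; adjusted p = 0.571 with an estimated correlation), and 9 of 25 passed when adjusted over the list alone, among them Hspa5, Manf and Creld2 with log2 fold changes of 0.50, 0.46 and 0.56. Immediate early genes had a median of -0.46 (camera adjusted p = 0.000435; adjusted p = 0.867 with an estimated correlation). Of these, 6 of 24 passed when adjusted over the list alone, and the list's median relative to controls was 0.02, -0.93 and -0.78 in stress replicates 1, 2 and 3. Choroid plexus markers had a median of 1.19 (camera adjusted p = 0.000147; adjusted p = 0.724 with an estimated correlation), and 5 of 13 passed when adjusted over the list alone. Ttr, which encodes the transport protein transthyretin of the choroid plexus, had 3.67, 492 and 320 CPM in stress replicates 1, 2 and 3 and at most 5.8 CPM in controls (log2 fold change 6.94, edgeR adjusted p = 0.465, and 0.0191 with the replicate block), and the list's median relative to controls was -0.08, 1.34 and 1.16 in the same order. Astrocyte markers were higher with a median of 0.16 (camera adjusted p = 0.000435; adjusted p = 0.62 with an estimated correlation), a call lost without stress replicate 1 (adjusted p = 0.0631). Thalamic and hypothalamic markers were higher with a median of 0.31 (camera adjusted p = 0.0436; adjusted p = 0.571 with an estimated correlation), and cortical markers were lower with a median of -0.36 (camera adjusted p = 0.00909; adjusted p = 0.752 with an estimated correlation). Leaving out control replicate 2 ended both calls, as did leaving out stress replicate 1 for the former and stress replicate 2 for the latter, with an adjusted p of up to 0.166 and 0.0883. Mitochondrially encoded mRNAs were lower with a median of -0.30 (camera adjusted p = 0.000435; adjusted p = 0.724 with an estimated correlation), a call lost without control replicate 3 (adjusted p = 0.0729).

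Of 42 lists tested in the brain, 9 passed with camera and 13 with the replicate block, where the largest adjusted p of these 9 was 0.00285. The lists added with the block were red cell markers, oligodendrocyte genes, hippocampal region markers and meningeal markers (camera adjusted p = 0.00453, 0.00419, 0.0194 and 0.00527 with the block, and 0.0719, 0.0719, 0.0719 and 0.126 without). With the block and an estimated correlation their adjusted p was 0.707, 0.868, 0.707 and 0.707. Striatal markers differed between replicates of both groups, with list medians of 2.65 in control replicate 3 and 1.87 in stress replicate 3, against -1.50 to -0.28 in the other 4 libraries. Without stress replicate 3, 15 lists passed, and without stress replicates 2 and 3, in a fit added after the data were seen, 14 lists and 0 genes passed in edgeR and camera.

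**Figure D2:**
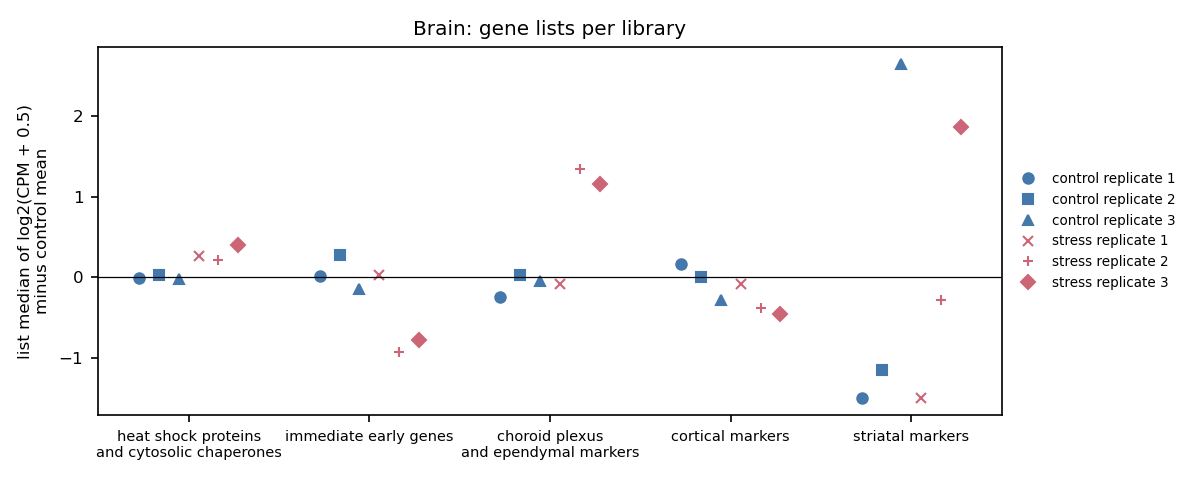
Median of log2(CPM + 0.5) of 5 gene lists in each brain library minus the mean of the controls (y axis), 1 symbol per library. Stress replicates 2 and 3 had choroid plexus medians of 1.34 and 1.16, and striatal markers were highest in control replicate 3 and stress replicate 3.

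The testis comparison asked for the same differences in the male reproductive tissue. Genes of ribosomal proteins, of oxidative phosphorylation and of antigen presentation were higher in stress testis as lists, and mitochondrially encoded mRNAs, sperm flagellum genes and cell cycle genes were lower. All 8 list calls of camera in testis were lost with an estimated correlation (adjusted p between 0.786 and 0.877). Ribosomal protein genes were higher in 75 of 76 members, with a median log2 fold change of 0.34 (camera adjusted p = 4.97e-14; adjusted p = 0.786 with an estimated correlation). Without stress replicate 2 that median was 0.192 (camera adjusted p = 4.56e-09). Reads of rRNA-like and 7S RNA genes, counted together, took 0.6713%, 0.9277% and 0.1182% of counts in stress replicates 1, 2 and 3 and 0.1522% to 0.345% in controls. Rps13 had 43.04 ± 5.514 CPM in control and 76.83 ± 12.25 CPM in stress (n = 3 per group) and did not pass over all genes (edgeR adjusted p = 0.272), and 1 member passed when adjusted over the list alone. Nuclear genes of oxidative phosphorylation were higher in 48 of 52 members, with a median of 0.26 (camera adjusted p = 4.79e-08; adjusted p = 0.786 with an estimated correlation). Without stress replicate 2 it was 0.171 (camera adjusted p = 1.5e-05). Antigen presentation genes were higher in 16 of 17 members, with a median of 0.60 (camera adjusted p = 7.23e-06; adjusted p = 0.786 with an estimated correlation), and Cd74 and H2-Q4 had log2 fold changes of 1.44 and 1.25 without passing over all genes (edgeR adjusted p = 0.422 for both). Lymphocyte markers had a median of 0.42 without passing (camera adjusted p = 0.0599, and 0.0377 with the replicate block; adjusted p = 0.905 with an estimated correlation and the block), with list medians of 0.289 to 0.318 in stress libraries and at most 0.076 in controls.

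Interferon-stimulated genes were higher in testis with a median of 0.38 (camera adjusted p = 0.0076; adjusted p = 0.786 with an estimated correlation), a call lost without control replicate 2 or stress replicate 2 (adjusted p of up to 0.0975). Sperm flagellum genes were lower in 22 of 31 members with a median of -0.16 (camera adjusted p = 0.0076; adjusted p = 0.877 with an estimated correlation), and Spag17 and Spag16 had log2 fold changes of -0.49 and -0.30. The flagellum median lay at percentile 3.42 of random lists matched on coding transcript length and expression, inside their central range, and at percentile 1.85 of lists matched on gene length, outside it. Without stress replicate 2 it was -0.088. Cell cycle genes were lower with a median of -0.07 (camera adjusted p = 0.0241; adjusted p = 0.786 with an estimated correlation), a call lost without control replicates 2 or 3 or stress replicate 2 (adjusted p of up to 0.0849). Receptors and enzymes of glucocorticoid action were lower with a median of -0.19 (camera adjusted p = 0.0303; adjusted p = 0.786 with an estimated correlation), a call lost without control replicates 1 or 3 or stress replicate 1 (adjusted p of up to 0.0802) and with the replicate block (0.0516). Mitochondrially encoded mRNAs were lower with a median of -0.47 (camera adjusted p = 0.00137; adjusted p = 0.877 with an estimated correlation), a call lost without stress replicate 2 (adjusted p = 0.246). In that library these mRNAs took 0.59% of counts, against 1.02% to 1.44% in the other 5 testis libraries. Its list medians relative to controls were -1.67 for mitochondrial mRNAs, 0.57 for ribosomal proteins, 0.90 for antigen presentation and 0.90 for macrophage markers. Lists of steroidogenesis, Sertoli cells, spermatogonia, meiotic prophase and round spermatids did not pass (camera adjusted p = 0.61, 0.0796, 0.876, 0.0588 and 0.869). With the replicate block the list of meiotic prophase did (camera adjusted p = 0.0377; adjusted p = 0.905 with an estimated correlation).

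Of 19915 genes tested in testis with edgeR, 1 was higher and 3 were lower, and DESeq2 called 29 and 32. An unadjusted p under 0.05 was found for 2337 genes in edgeR against 995.8 expected by chance. Control and stress values did not overlap in 20.9% of the tested genes, where chance gives 10% on average. Fras1, which encodes an extracellular matrix protein, fell from 6.42 ± 1.302 to 1.02 ± 0.0541 CPM, a log2 fold change of -2.66 ± 0.23 (SE, edgeR adjusted p = 0.0142). Afm, which encodes the vitamin E-binding protein afamin, fell from 15.01 ± 3.614 to 3.31 ± 0.491 CPM, a log2 fold change of -2.18 ± 0.21 (edgeR adjusted p = 0.0193). The other called genes, chosen after their values were seen, were the long non-coding RNA 1700084F23Rik, which fell by 1.12 on the log2 scale, and the pseudogene Gm6969, which rose from 0.142 ± 0.193 to 14.38 ± 6.71 CPM. Genes with the smallest p that did not pass were Tmem37, Rps13, Amd2 and Hapln1 on the higher side (log2 fold changes 1.89, 0.84, 1.57 and 3.91) and Aldh3a1, Zeb1 and Speer1 on the lower side (-1.50, -0.72 and -1.02). Fkbp5, Tsc22d3, Per1, Sgk1 and Nr3c1 had log2 fold changes of 0.12, 0.31, 0.25, 0.28 and -0.37 and did not pass (edgeR adjusted p = 0.744, 0.488, 0.422, 0.634 and 0.422). The counts were 0 higher and 0 lower without control replicate 3 or stress replicate 1, 0 and 1 without control replicate 1, 8 and 13 without stress replicate 2, and 2 genes were higher without stress replicate 3. Fras1 was lost without control replicate 3 or stress replicate 1 (adjusted p of up to 0.122), and Afm without these or control replicate 1 (up to 0.379). Without stress replicate 3, 15 lists passed in place of 8.

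**Figure D3:**
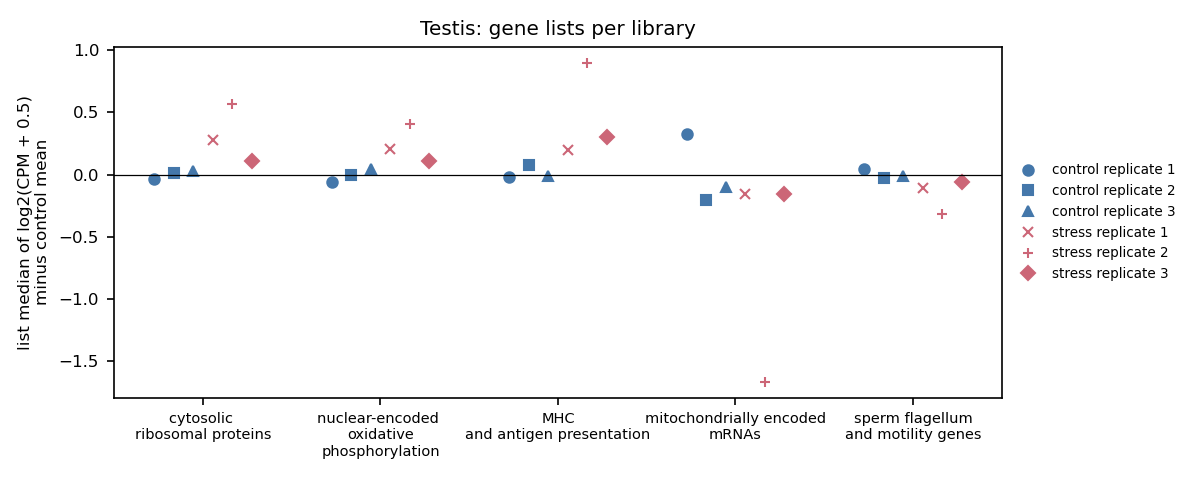
Median of log2(CPM + 0.5) of 5 gene lists in each testis library minus the mean of the controls (y axis), 1 symbol per library. Ribosomal protein medians were 0.28, 0.57 and 0.11 in stress replicates 1, 2 and 3, and mitochondrial mRNAs were lowest in stress replicate 2 at -1.67.

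The comparison between tissues asked whether the effect of stress differs from tissue to tissue. The stress effect on Fkbp5 and Tsc22d3 was larger in liver than in testis, by 1.54 ± 0.28 and 1.44 ± 0.28 on the log2 scale (SE, edgeR interaction adjusted p = 0.0279 and 0.0367, and 0.019 and 0.0988 with animal as a block). Between liver and brain the difference was 1.52 ± 0.25 for Tsc22d3 (adjusted p = 0.0204, 0.0614 with the block) and 0.81 ± 0.29 for Fkbp5, which did not pass (edgeR interaction adjusted p = 0.217, 0.131 with the block). The stress effect differed between liver and brain in 73 of 13079 genes, 27 with the block, of which 24 were in common. The genes with the smallest unadjusted p were Acsl3 (difference -1.39), Fam198a (-2.57), Trpm2 (1.72), Tchh (-2.62) and Cxcl14 (1.86), with edgeR adjusted p between 0.00143 and 0.00493. Acsl3, which activates long-chain fatty acids, had log2 fold changes of -1.29 in liver and 0.10 in brain. The stress effect differed between liver and testis in 110 of 12952 genes, 39 with the block, of which 31 were in common. The genes with the smallest unadjusted p were C4a (1.92), Hal (-1.65), Afm (2.01), Zbtb16 (3.30) and Aqp8 (-3.11), each with an edgeR adjusted p of 0.00626, which further genes such as Tchh shared. Hal, the first enzyme of histidine breakdown, had log2 fold changes of -0.78 in liver and 0.86 in testis. All 10 of these genes passed with the block (adjusted p of up to 0.0432). Between brain and testis 0 of 15387 genes differed in edgeR, with 1615 at an unadjusted p under 0.05, 0 with the block and 0 with limma-voom. The genes with the smallest p there were A2m, Fras1, Ccdc117, Gata3 and Ccdc60 (edgeR interaction adjusted p = 0.184 each). The count between liver and brain was 41 without control animal 1, 23 without control animal 2, 38 without stress animal 1 and 8 without stress animal 3, and between liver and testis it was 57, 10 and 11 without control animals 1, 2 and 3 and 49 and 11 without stress animals 1 and 3. Between brain and testis it was 4 without stress animal 2.

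Gm6969 was the 1 gene that edgeR called in each pair of tissues, higher in all 3. At an unadjusted p under 0.01, liver and brain had 23 genes higher in common against 5.58 expected (Fisher's exact test, one-sided p = 7.38e-09) and 9 lower against 2.63 expected (p = 0.00123, Fisher's exact test), with 4 in opposite directions. The shared higher genes included Fkbp5, Per2, the chaperones Hspb1, Stip1, Ahsa1 and Chordc1, and the endoplasmic reticulum genes Creld2 and Sdf2l1. The shared lower genes included Fosb, mt-Nd5 and mt-Nd6. Liver and testis had 13 higher against 5.43 expected and 3 lower against 3.41 expected, and brain and testis had 7 higher against 2.05 and 3 lower against 1.02 (Fisher's exact test, one-sided p = 0.00311, 0.667, 0.00453 and 0.0821). These p values assume independent genes and tissues. The tissues were taken to come from the same 6 animals, whose differences from each other can also give shared genes.

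**Figure D4:**
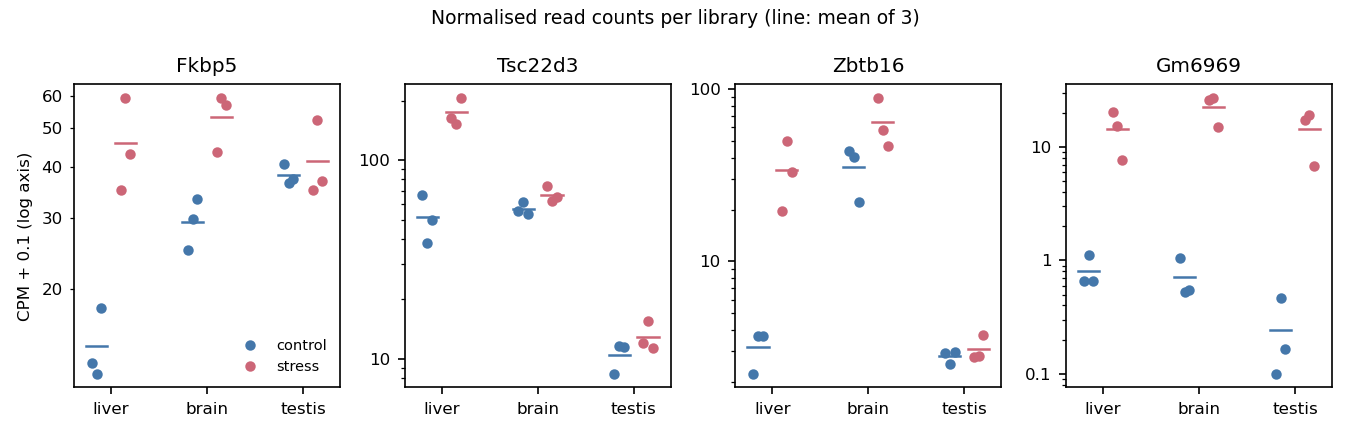
Normalised read counts (CPM + 0.1, log axis) of Fkbp5, Tsc22d3, Zbtb16 and Gm6969 in each library by tissue, with a line at the mean of 3 libraries. Stress values of Fkbp5 in liver lay between 34.98 and 58.99 CPM, above the control values of 12.29 to 17.85 CPM.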

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

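The results here are differences of the stress effect between tissues that passed the interaction test, which was chosen before the data were examined. The number of genes that differed was 73 between liver and brain and 110 between liver and testis. Of the 10 splits of the 6 animals, 1 gave as many genes for liver and brain (73 for the real split, at most 1 for the others) and 1 for liver and testis (110, at most 3 for the others). For brain and testis the real count was 0, which all 10 splits reach by construction, so that comparison decides nothing, and the highest other count was 20. With 10 splits no share under 0.05 can be had.

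Between liver and brain the difference on the log2 scale was -1.39 for Acsl3, -2.57 for Fam198a, 1.72 for Trpm2, -2.62 for Tchh and 1.86 for Cxcl14, the genes with the smallest unadjusted p. It was -3.98 for Eps8l1, 3.996 for Hapln1, -3.16 for Pnpla3 and -3.16 for Socs3, which passed with animal as a block as well. It was 2.22 for Angptl4, 1.52 for Tsc22d3 and 2.60 for Zbtb16, which did not pass with the block (adjusted p = 0.11, 0.0614 and 0.128, edgeR).

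Between liver and testis the difference on the log2 scale was 1.92 for C4a, -1.65 for Hal, 2.01 for Afm, 3.30 for Zbtb16 and -3.11 for Aqp8, the genes with the smallest unadjusted p. It was -3.18 for Fosb, 1.54 for Fkbp5, -2.60 for Tchh and -4.29 for Socs3, which passed with the block. It was -4.04 for Fam83f and 1.44 for Tsc22d3, which did not (adjusted p = 0.115 and 0.0988, edgeR). The difference for Afm came with a lower level in stress testis (log2 fold change -2.18) beside -0.16 in liver. No explanation was tested for these differences.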

How the results depend on the processing

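No gene called within a tissue changed direction under the alternatives run for it. No called list passed in the other direction under those run for lists (the estimated correlation, fry, other scalings, the block and leaving out libraries). For a list that no longer passed, the direction was not recorded under each of these. No alternative chosen before the data were seen was left unrun, and the cause of the changes below was not tested. Fits with DESeq2 size factors in edgeR, the stricter filter and TMM within each tissue kept every count within 1.5 times. In liver, the genes higher (140) and lower (92) numbered 450 and 408 without a filter, 471 and 381 with DESeq2, 90 and 53 on log2(TPM + 1), 75 and 54 on log2(TPM + 0.1), 474 and 623 with all 18 libraries in 1 fit and 261 and 214 with the replicate block, and 59 lower genes also changed 2-fold. Leaving out each library gave 15 to 157 higher and 16 to 134 lower genes, and 28 of the 232 calls remained without stress liver replicate 3. In brain, the genes higher (1) and lower (0) numbered 2 and 0 without a filter, 93 and 44 with DESeq2, 0 and 0 with limma-voom, 2 and 0 with all 18 libraries in 1 fit, 17 and 5 with the replicate block, and 0 to 1 and 0 when each library was left out. Without stress brain replicates 2 and 3 together, chosen after seeing the data, 0 genes were higher and 0 lower, 14 lists changed, and the lone stress library was assumed to vary like the controls. In testis, the genes higher (1) and lower (3) numbered 10 and 15 without a filter, 29 and 32 with DESeq2, 0 higher with limma-voom, 1 lower on log2(TPM + 1), 0 and 0 on log2(TPM + 0.1), 4 higher with all 18 libraries in 1 fit, 2 higher with the replicate block, and 0 to 8 and 0 to 13 when each library was left out. Changed lists in liver (14), brain (9) and testis (8) numbered 0, 0 and 0 with an estimated correlation, 2, 0 and 0 with fry, and 12 to 15, 8 to 15 and 6 to 15 when each library was left out. Genes whose effect differed between liver and brain (73) and between liver and testis (110) numbered 27 and 39 with animal as a block, 40 and 45 with limma-voom, 38 and 45 with animal as a random effect, and 8 to 73 and 10 to 152 when each animal was left out. For brain and testis (0) leaving out each animal gave 0 to 4. Genes changed in the same direction (1 in each pair) numbered 18, 5 and 3 with DESeq2 and 32, 16 and 10 at an unadjusted p under 0.01, for liver and brain, liver and testis, and brain and testis. Over the named genes, without those named only as list members, and the 6 fits with a library left out, 50 values in liver and 5 in testis were weaker. All called lists kept the sign of their median under each scaling tried. Depth was at least 27.85 megacounts per library and limits genes with few counts, while replicates of a group differed by more than counting error (chi-square per degree of freedom of at least 4.64).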

Other observations

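Tests chosen only after the result was seen were both tests of the choroid plexus markers, the count of repeating genes limited to a 2-fold range, the description of the brain split by striatal markers and the search for genes that separate the animals in all 3 tissues.

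Liver and brain had list calls in the same direction for chaperones and for immediate early genes, of which members passed as single genes in liver and none did in brain, where Btg2 and Npas4 passed with the replicate block (edgeR adjusted p = 0.012 for both). Chaperone genes were higher as a list, with medians of 0.61 in liver and 0.30 in brain (adjusted p = 0.631 and 0.571 with an estimated correlation), and -0.02 in testis, where the list did not pass (camera adjusted p = 0.83). Immediate early genes were lower as a list, with medians of -1.79 and -0.46 (adjusted p = 0.631 and 0.867 with an estimated correlation), and -0.05 in testis (camera adjusted p = 0.506). Mitochondrially encoded mRNAs had medians of -0.33 in liver, -0.30 in brain and -0.47 in testis (adjusted p = 0.631, 0.724 and 0.877 with an estimated correlation), and in testis without stress replicate 2 the median was -0.188 and the list did not pass (camera adjusted p = 0.246). Whether the lists differ between tissues was not tested.

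Brain genes of regional identity varied along the replicate numbers. A split of the 6 brain libraries into control replicates 1 and 2 with stress replicate 1 against the rest called 108 genes, 67 higher and 41 lower, against 1 for the real split, which points to a structure of the samples that is not the stress group. In that split 14 of 14 striatal markers were higher in the second set, with a median log2 fold change of 3.45, and 3 of them passed. Of the 10 splits, 4 gave at least as many genes as the real one in brain, with the real value 1 and the highest other 108. If the replicate numbers pair the brain samples, the splits that part all 3 pairs called 1 gene for the real split and 0 for each of the other 3. That pairing was read from correlations in these same libraries and is not given by the labels, so these splits lend the calls with the block no separate support. For liver 1 of the 10 splits gave as many genes (232 for the real one, at most 2 for the others) and for testis 1 (4, at most 1 for the others). With 10 splits no share under 0.05 can be had.

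Choroid plexus markers were higher in stress brain. Choroid plexus tissue taken along with stress replicates 2 and 3 stays open: these libraries were the 2 highest of 6 for 10 of the 13 tested markers, among them Ttr with 492 and 320 CPM, but they were singled out from these same markers, so the count does not bear on the cause. A rise in every stress animal was met by 5 of 13 markers, which were higher in stress replicate 1 than in all controls, Prlr and Otx2 among them, so it cannot be told apart from a few cells in that library. Against the control of the same number, Ttr, Kl, Kcnj13, Clic6, Otx2, Sostdc1, Prlr and Foxj1 were higher in each stress library, and the other tested markers were not. The margin in replicate 1 was small for some, such as Kcnj13 with 0.746 against 0.714 CPM, and these pairs were not tested. A response of the choroid plexus itself in 2 of the 3 stress animals stays open and was not tested.

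Ribosomal protein and oxidative phosphorylation genes were higher in stress testis, and their short transcripts could have followed a length trend between the groups. Against lists matched on gene length and expression, both medians lay at percentile 100 of 10000 random lists. Against lists matched on coding transcript length, the lower of both lay at percentile 99.99. The latter test was added once the gene length result was known and before its own result was seen. These values argue against length as the whole cause, although the matched lists were themselves higher, with medians of 0.15 and 0.13 on transcript length. The random lists were drawn from pools that held members of the tested lists too, so these medians are not free of them. The draws also took genes singly, so the percentiles leave out how such genes vary together. Without stress testis replicate 2 the ribosomal protein median was 0.192 with a camera adjusted p of 4.56e-09 at the preset correlation, but it was 0.34 with it. The list thus stayed higher without that library, which goes against that library as the only source. How much of the rise it gave is not settled, since no fit with an estimated correlation left it out. The estimated correlation between the genes ended the calls (adjusted p = 0.786). Reads of rRNA-like and 7S RNA genes, counted together, took 0.6713%, 0.9277% and 0.1182% of counts in stress testis replicates 1, 2 and 3 and 0.1522% to 0.345% in controls. Within stress this was the same order as the ribosomal protein medians of 0.28, 0.57 and 0.11. Stress replicate 3, with the lowest share of all 6, still lay above the control medians of -0.034, 0.013 and 0.031. RNA quality, which was not tested, a difference between single animals and an effect of stress therefore stay open.

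Gm6969, a pseudogene of Cox7a2l, and Amd2, a close relative of Amd1, separated the stress from the control animals in all 3 tissues. Among 12496 genes tested in all 3, they were the only ones to do so by at least 2-fold in each, in the same direction and with the offset used. Genes that separated the animals by less than 2-fold were not counted. Under the same limits other splits of the animals gave at most 2 genes, among them Rps13-ps1. Reads shared with the parent gene at a constant share were excluded, since the log2 fold changes exceeded those of Cox7a2l by at least 9.97 SE and those of Amd1 by at least 3.45 SE in every tissue, although the counting rule for reads with several matches is not known here and another rule could change the values of both genes. Reads moved from Cox7a2l to Gm6969 by a sequence difference between the animals cannot be told apart from a rise: Cox7a2l was lower in 3 of 3 tissues, and the sum of both was 87.4 and 83.1 CPM in control and stress liver and 101 and 101 CPM in brain, but higher in testis, 44.1 and 52.4 CPM, by 2.37 SE. For Amd2 a shift of reads from Amd1 was not tested and stays open. The sum of Amd1 and Amd2 was 37.92 and 51.23 CPM in control and stress liver, 114 and 115.6 in brain and 56.36 and 57.72 in testis. The share of Amd2 in that sum went from 2.48%, 3.04% and 2.4% in control to 6.87%, 7.86% and 6.97% in stress, in the same order of tissues. Genes whose differences between animals of a group repeat in the 3 tissues, as genetic differences would give, numbered 24, with a median of 14 and a highest of 27 in 100 permutations of the animals, and among genes with a 2-fold range 3, with a median of 0 and a highest of 3, all 3 of them pseudogenes. Permutations reached both counts, which compare animals within a group, so the counts do not decide on a difference between the groups. Gm6969 itself was lowest in stress replicate 3 of each tissue, with 7.689 CPM in liver, 14.91 in brain and 6.682 in testis. Stress replicates 1 and 2 had 20.34 and 15.35 CPM in liver, 26.2 and 26.97 in brain and 17.43 and 19.02 in testis. This repeat, seen after the fact, was not tested and does not tell a genetic difference from a response that varies between animals. A genetic difference between the groups of animals stays open as a source of Gm6969 and Amd2. Such a difference was confounded with stress, as it was for every other call between the groups.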
